A study of Escherichia coli K-12 with 12 samples.

How the data were processed

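Messenger RNA levels were measured in Escherichia coli K-12 by sequencing total RNA from 12 cultures. The strains were BW30270, an MG1655 derivative with the rph gene restored, and its pdeL deletion derivative. Per the labels' protocols, cultures grew at 37 °C in 10 ml LB medium with kanamycin at 25 µg/ml, starting at an OD600 of 0.08. IPTG, an inducer of lac-type promoters, was added to 1 mM at an OD600 of 0.35, and 2 ml were harvested 15 minutes later. RNA was treated with DNase and then with terminator exonuclease (TEX), which degrades RNA with a 5′ monophosphate. That step enriches primary transcripts and lowers ribosomal RNA, so a value reflects both the amount of a transcript and its share of unprocessed 5′ ends. Libraries were prepared with a TruSeq kit without poly-A selection.

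The deposited values are raw counts per gene, with no normalization by the authors, in 4419 rows per library named by locus tag. The submitters' processing notes name Bowtie2 2.3.4.2, HTSeq 0.9.1, DESeq2 2.11.40.2 and the genome build ASM584v2, without saying which step used which. The strand setting of the counting and the treatment of reads that match several places are not given in the sources used here. Reads from a gene and an overlapping or antisense neighbour can therefore not be told apart. Locus tags were matched to a RefSeq gene table of the same build, which gave symbols and coordinates for 4414 tags. The other 5 tags held at most 0.00086% of the counts of any library.

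Groups and replicate numbers were taken from the sample titles. The series describes the replicates as biological, with 3 libraries in each of 4 groups. Libraries of a group differed by more than counting noise, with a chi-square per degree of freedom of 7.59 or more in every pair, so none was counted as a duplicate. Total counts ran from 464296 to 687686 per library, and ribosomal RNA genes took between 30.2% and 48.1% of them. The median gene had a mean count of 4.67 per library, and 2245 genes had a mean count under 5. Small changes in most genes are below what this depth can show, and counting floors cover counting error only.

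Counts were tested with edgeR 4.0.16 in R 4.3.3, using the quasi-likelihood F test, TMM factors and the filterByExpr filter by group with its minimum count of 10 and minimum total of 15. That left 1911 genes. A single fit with a mean per group held all 12 libraries, tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The standard error of a log2 fold change is its size divided by the square root of F. Normalised counts are CPM, counts scaled by library size and TMM factor, as mean ± SD of 3 libraries. Where a group had no count of a gene, folds were computed against a floor of 3 counts over the group. Operon sums, a choice made after seeing the data, were compared by a two-sided exact permutation test on log2(CPM + 0.5), for which 3 against 3 libraries cannot give a p below 0.10.

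Of 32 gene lists fixed before the data were examined, 21 had at least 3 tested members. These were tested with camera (limma 3.58.1) at a preset correlation of 0.01, again with an estimated correlation, and with fry. The remaining 11 lists are not reported as groups, apart from members named singly. List members yghF, yghE, bcsQ, ilvG and gatC had no match and were not analysed here. Named genes followed a rule, also fixed beforehand. It takes pdeL, fliF to fliK and sslE (listed under its other symbol yghJ) whatever their values. To these it adds up to 12 rising and 12 falling genes past the threshold with libraries that do not overlap. Where fewer than 5 other genes pass, it takes the 5 with the smallest p, and for each list that passes up to 4 members. The lac genes and the neighbours of pdeL complete it. The fliFGHIJK list comes from what is known of PdeL, and the study may have drawn it from these libraries, so its direction is not independent evidence.

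Alternatives fixed beforehand were other size factors, other filters on low counts, DESeq2 1.42.0, limma-voom, fits with only the groups compared, the replicate number as a block, library sizes without ribosomal RNA, tRNA and pdeL, and leaving out each library in turn. Because the libraries numbered 1 stood apart, a term for that number, fits without those 4 libraries, and DESeq2 and limma-voom fits with a block or that term were added after seeing the data. The tests were checked on simulated counts for plasmid-borne PdeL against the deletion control over the same 1911 genes. Counts with library effects shared by number were drawn from the fit with the replicate block. With library effects shared by number, the edgeR test recovered 4.2% of 2-fold, 49.0% of 4-fold and 73.3% of 8-fold changes, with 0.2% of its calls false, against 0.4% for DESeq2. Without such effects it recovered 7.5%, 59.4% and 77.9%, with 4.8% of its calls false, against 9.0% for DESeq2.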

Results

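PdeL is a LuxR-type transcription regulator that also degrades the second messenger c-di-GMP, and the series set out to find which genes it controls. The 12 libraries fall into 4 groups of 3: the wild type with the empty vector (wt+ctrl), the pdeL deletion with the empty vector (delta-pdeL+ctrl), and the deletion with plasmid-borne PdeL (delta-pdeL+PdeL) or with a PdeL-cI fusion (delta-pdeL+PdeLDBD_cIc). Mean total counts were 658257 ± 26861 in wt+ctrl, 598102 ± 44040 in delta-pdeL+ctrl, 611410 ± 62071 in delta-pdeL+PdeL and 577625 ± 107388 in delta-pdeL+PdeLDBD_cIc (SD, n = 3 each).

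The deleted and plasmid-borne gene was read first. pdeL (b0315, positions 332371 to 333459 of the chromosome in build ASM584v2) had 4, 21 and 12 counts in the wt+ctrl libraries and 0 counts in each delta-pdeL+ctrl library. With plasmid-borne PdeL it had 4969, 4888 and 2948 counts, and with the fusion 336, 913 and 604. Pooled over a group and set against a floor of 3 counts in delta-pdeL+ctrl, pdeL was at least 11.4-fold higher in wt+ctrl, at least 4150-fold higher in delta-pdeL+PdeL and at least 616-fold higher in delta-pdeL+PdeLDBD_cIc. The fusion holds only part of pdeL, so its counts are not comparable gene for gene with those of the full-length gene.

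Libraries numbered 1 stood apart from those numbered 2 and 3. An edgeR test of number 1 against 2 and 3 was chosen after the values were seen. Past the threshold, 264 of 1911 genes were higher in number 1 and 172 were lower. On the first principal component of log2 CPM, which held 53.0% of the variance, number 1 lay at -32.2 in delta-pdeL+ctrl, -31.9 in delta-pdeL+PdeL and -44.8 in delta-pdeL+PdeLDBD_cIc. The wt+ctrl library numbered 1 lay at -0.55, and the other libraries between 2.29 and 19.9. Tryptophanase gene tnaA had 315, 391 and 449 counts in the libraries numbered 1 of the deletion strain, against 9 in wt+ctrl number 1 and at most 6 in any other library. lacZ, the β-galactosidase gene, had 271, 379 and 351 counts there, 46 in wt+ctrl number 1 and between 16 and 54 elsewhere.

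**Figure D1:**
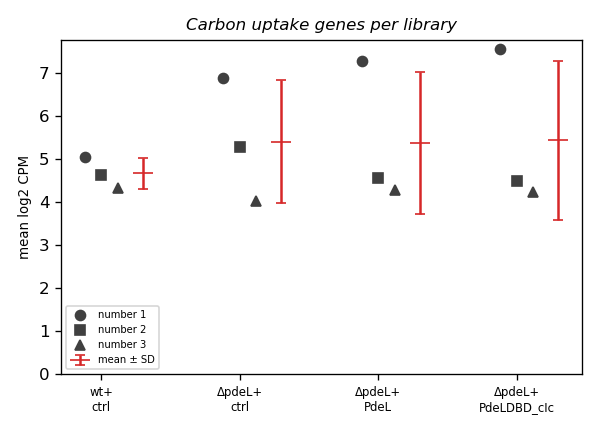
Mean log2 CPM of 30 genes for the uptake of sugars and sugar alcohols (vertical axis) per library and group; symbols give the replicate number and red bars the mean ± SD of 3 libraries. Number 1 had 6.88, 7.26 and 7.56 in the groups of the deletion strain and 5.04 in wt+ctrl, and the other libraries had 4.03 to 5.27.

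Deleting pdeL, with the empty vector in both strains, addressed what chromosomal pdeL does under these conditions. The fliFGHIJK operon, which encodes the flagellar basal-body ring, switch and export parts and spans positions 2013229 to 2019513, summed to 375 ± 79.2 CPM in delta-pdeL+ctrl and 352 ± 35.6 CPM in wt+ctrl (SD, n = 3, two-sided exact permutation p = 0.80). yghJ (also called sslE, b4466, positions 3114550 to 3119112), which encodes a secreted mucin-degrading lipoprotein, had 73.6 ± 7.65 CPM against 83.0 ± 6.22 CPM (SD, n = 3; log2 fold change -0.17 ± 0.22 SE, edgeR adjusted p = 0.991). The iron-sulfur carrier gene erpA had 36.0 ± 7.35 CPM against 80.8 ± 15.4 CPM and was not past the threshold (log2 fold change -1.17 ± 0.27 SE, adjusted p = 0.991). The others with the smallest p, yfcE, yhfK, yebO and rsxE, were not past it either. No gene passed in the edgeR test over 1911 genes, with 61 at an unadjusted p under 0.05, where 95.6 would fall by chance. All 5 comparisons had fewer than that, from 40 to 82. In the simulations with library effects shared by number, 0.2% of the edgeR calls were false, so the test was conservative there. A count below chance therefore does not show that nothing changed. limma-voom also called 0 genes, and DESeq2 called 1, pdeL itself (log2 fold change -5.93, adjusted p = 0.0176). pdeL had a fitted log2 fold change of -6.53 and an adjusted p of 0.174 in the edgeR test, and passed it without wt+ctrl replicate 1 (adjusted p = 0.0332, with a range of 0.0105 to 0.979 over the alternatives). Of the 21 lists, 0 passed in camera, with 4 at an unadjusted p under 0.05, and 0 passed with an estimated correlation or in fry. The lac operon list had a median log2 fold change of 2.26 and the sugar alcohol and ribose list 1.24. Both lists were higher in the libraries numbered 1, by medians of 3.43 and 2.62. There they passed camera at the preset correlation (adjusted p = 0.00849 and 4.1e-11), but not with an estimated correlation (adjusted p = 0.303 each).

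Adding plasmid-borne PdeL to the deletion strain addressed which transcripts change when the protein is made from a plasmid. yghJ rose from 73.6 ± 7.65 to 438 ± 15.1 CPM, a fitted 5.94-fold rise (SD, n = 3; log2 fold change 2.57 ± 0.23 SE, edgeR adjusted p = 0.00018). fliFGHIJK summed to 40.7 ± 20 CPM against 375 ± 79.2 CPM, a 9.22-fold lower mean (SD, n = 3, two-sided exact permutation p = 0.10, the smallest the design allows). Within the operon fliF, the basal-body ring gene, had 18.5 ± 13.1 CPM against 219 ± 52.4 CPM and a log2 fold change of -3.53 ± 0.63 SE. The switch gene fliG had -3.23 ± 0.57, fliH -2.63 ± 0.48 and the export ATPase gene fliI -2.40 ± 0.52.

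Over all genes tested, fliF, fliG and fliH each had an edgeR adjusted p of 0.0697 and fliI 0.161, and 0 of the 4 tested operon members passed. All 4 passed when adjusted over the list alone, on a list that is not independent evidence. fliJ and fliK had too few counts to be tested. As a list the operon fell, with a median log2 fold change of -2.93 (camera adjusted p = 1.9e-22, and adjusted p = 0.00628 with an estimated correlation). The size of the fall varied: the median was -3.91 without delta-pdeL+PdeL replicate 1 and -3.52 without the libraries numbered 1, and the summed CPM was lower 5.27, 7.92 and 24.9-fold in the libraries numbered 1, 2 and 3. The other class 2 flagellar genes fell as a list, with all 19 tested members below 0 and a median of -1.14 (camera adjusted p = 1.82e-18, adjusted p = 0.0618 with an estimated correlation). Among them flhB had a log2 fold change of -1.27 ± 0.37 and flgG -1.15 ± 0.39 (SE). The class 3 and chemotaxis list also fell, with all 22 tested members below 0 and a median of -1.24 (camera adjusted p = 8.99e-11, adjusted p = 0.733 with an estimated correlation). The class 3 sums differed by number in every group, and number 3 was lowest: 8328, 7985 and 1786 CPM in wt+ctrl numbers 1, 2 and 3, 12870, 9489 and 2139 in delta-pdeL+ctrl, 5944, 2694 and 175 with PdeL and 7410, 4836 and 280 with the fusion. Number 1 against 2 and 3 gave this list a median of 1.16 (camera adjusted p = 0.00102, adjusted p = 0.719 with an estimated correlation). Without number 1 the median of the list for PdeL against deletion was -1.85. Its summed CPM was lower 2.17, 3.52 and 12.2-fold in the libraries numbered 1, 2 and 3 (two-sided exact permutation p = 0.30). Its genes flgL and fliD had log2 fold changes of -1.71 ± 0.66 and -1.50 ± 0.89 (SE). In both lists 0 members passed over all genes and 0 adjusted over the list alone.

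The 5 other genes with the smallest p did not pass the edgeR test. wecA, which starts enterobacterial common antigen synthesis, had 40.2 ± 13.9 CPM against 131 ± 38.9 CPM (SD, n = 3; log2 fold change -1.71 ± 0.36 SE, adjusted p = 0.158). Its neighbour wzzE had a log2 fold change of -1.59 ± 0.36, the proline synthesis gene proB -1.20 ± 0.25, the enoyl reductase gene fabI -1.10 ± 0.26 and nudF 1.45 ± 0.36 (SE). With a term for the libraries numbered 1, chosen after seeing the data, the count of genes rose from 2 to 5, adding fliF and fliG (adjusted p = 0.0104 each) and wecA (0.0282). Over all alternatives the adjusted p ran from 9.87e-09 to 0.329 for fliF, 9.6e-05 to 0.590 for fliG and 0.000957 to 0.784 for wecA. Without those 4 libraries it was 9, of which 5 rose and 4 fell. Besides pdeL and yghJ, ydfZ (log2 fold change 3.44, adjusted p = 0.00377), grcA (3.02, 0.0208) and cspA (1.26, 0.043) were higher, and fliF, fliG, flgD and fabI were lower (-4.14, -4.12, -1.84 and -1.16). With all libraries ydfZ, grcA and cspA had adjusted p of 0.670, 0.879 and 1.00. ydfZ had 4.45, 93.7 and 132 CPM in the PdeL libraries numbered 1, 2 and 3. DESeq2 called 5, namely pdeL, yghJ, fliF, fliG and wecA.

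**Figure D2:**
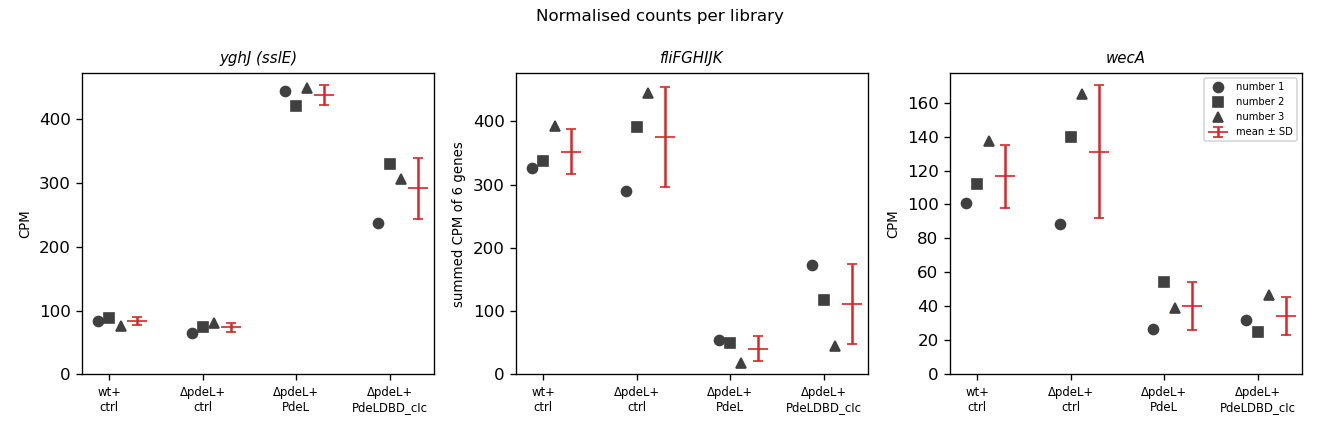
CPM of yghJ (left), summed CPM of the 6 fliFGHIJK genes (middle) and CPM of wecA (right) on linear axes from 0, per library and group; symbols give the replicate number and red bars the mean ± SD of 3 libraries. yghJ averaged 438 CPM with plasmid-borne PdeL and 73.6 CPM in the deletion control, and fliFGHIJK averaged 40.7 and 375 CPM.

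The PdeL-cI fusion was set against the same control. yghJ rose to 291 ± 48.1 CPM from 73.6 ± 7.65 CPM, a fitted 3.95-fold rise (SD, n = 3; log2 fold change 1.98 ± 0.22 SE, edgeR adjusted p = 0.00208). fliFGHIJK summed to 111 ± 63.6 CPM against 375 ± 79.2 CPM, a 3.37-fold lower mean (SD, n = 3, two-sided exact permutation p = 0.10, the smallest possible). fliF, fliG, fliH and fliI had log2 fold changes of -1.95 ± 0.58, -1.64 ± 0.51, -1.98 ± 0.46 and -1.35 ± 0.48 (SE). None of these 4 passed over all genes, with edgeR adjusted p of 0.451 for fliH and 0.998 for the others, and all 4 passed adjusted over the list alone. wecA had 34.3 ± 11.2 CPM against 131 ± 38.9 CPM (log2 fold change -1.92 ± 0.36 SE, adjusted p = 0.145), wzzE -1.85 ± 0.36 and wecB -2.02 ± 0.54. wecA was called in DESeq2 (adjusted p = 0.00918), with the term for the libraries numbered 1 (0.0196) and without those libraries (0.0418), and over all alternatives its adjusted p ran from 0.000403 to 1.00. erpA had 69.2 ± 3.52 CPM against 36.0 ± 7.35 CPM (log2 fold change 0.94 ± 0.27 SE) and the lactate dehydrogenase gene ldhA 0.90 ± 0.27, neither past the threshold (adjusted p = 0.998).

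The fliFGHIJK list fell with the fusion, with a median log2 fold change of -1.79 (camera adjusted p = 2.44e-12, adjusted p = 0.0372 with an estimated correlation). The call is lost in fry (adjusted p = 0.0553) and, with the term for the libraries numbered 1, at an estimated correlation (adjusted p = 0.111). Over all alternatives the adjusted p ran from 3.93e-14 to 0.226, and the median was -2.50 without the libraries numbered 1. The other class 2 genes fell as a list, all 19 below 0 with a median of -0.90 (camera adjusted p = 3.5e-14, adjusted p = 0.129 with an estimated correlation). The class 3 and chemotaxis list fell, all 22 below 0 with a median of -0.72 (camera adjusted p = 2.41e-05, adjusted p = 0.952 with an estimated correlation), with sums of 7410, 4836 and 280 CPM in fusion libraries 1, 2 and 3. The heat shock list rose, with 16 of 17 members above 0 and a median of 0.35 (camera adjusted p = 0.0139, adjusted p = 0.952 with an estimated correlation), groL at 0.47 ± 0.28 and lon at 0.44 ± 0.27 (SE). The heat shock list was higher in the libraries numbered 1 by a median of 0.396 (camera adjusted p = 0.0384, adjusted p = 0.719 with an estimated correlation). Without those libraries its median was 0.02 and its adjusted p 0.697. No member of the latter 3 lists passed adjusted over the list alone or over all genes. The 2 genes called were pdeL and yghJ. In a fit of only the compared groups yghJ was not called (adjusted p = 0.206), and in limma-voom pdeL was not (adjusted p = 0.0879). These are the highest over the alternatives, and the lowest were 2.3e-11 for yghJ and 5.44e-18 for pdeL.

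Both plasmid-borne proteins shared those 2 calls, in the same direction. pdeL is carried by both plasmids and had to be shared, which leaves yghJ. In DESeq2 and with the term for the libraries numbered 1 the shared calls were 3, with wecA. The 3 control libraries are too few to split. Simulated unchanged groups against the shared control gave 0.01 shared calls on average in 100 simulations, and with pdeL set aside independent lists would share 0.000524. Log2 fold changes of the other genes correlated across genes at 0.613 against a simulated mean of 0.506, and genes are not independent replicates. The covariance was 0.155 against a simulated 0.244, a difference of -0.089. With the fusion set against wt+ctrl, which shares no library with the PdeL comparison, the correlation was 0.221 and the covariance 0.089, and simulated covariance averaged 0.002. yghJ was called there too, with a log2 fold change of 1.81 (edgeR adjusted p = 0.00469). The simulations drew each library independently, without effects shared by number, so variation by number entered them as independent noise. A shift by number equal in every group would largely cancel, since each group held numbers 1, 2 and 3. The shift of number 1 differed, however: mean log2 CPM of 30 sugar uptake genes was higher by 0.567 in wt+ctrl and 3.20 with the fusion. These correlations and covariances therefore cannot separate effects common to the proteins from number shifts that differ between groups.

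PdeL and the fusion were also compared directly, which tests the difference of their effects. fliFGHIJK summed to 40.7 ± 20 CPM with PdeL and 111 ± 63.6 CPM with the fusion (SD, n = 3, two-sided exact permutation p = 0.30). fliF had a log2 fold change of -1.58 ± 0.61 and fliG -1.59 ± 0.59, while yghJ had 0.59 ± 0.21 (SE, edgeR adjusted p = 0.999 each). The fliFGHIJK list was lower with PdeL, with a median of -1.31 (camera adjusted p = 1.57e-05, adjusted p = 0.375 with an estimated correlation), and 2 of its 4 members passed adjusted over the list alone. The class 3 and chemotaxis list was lower too, with 21 of 22 members below 0 and a median of -0.505 (camera adjusted p = 0.0104, adjusted p = 0.964 with an estimated correlation) and sums that were lowest in number 3 of both groups. Its member flgL had -1.16 ± 0.66 and ycgR, a c-di-GMP-binding flagellar brake gene, 1.05 ± 0.93 (SE). Without delta-pdeL+PdeLDBD_cIc replicate 1 the fliFGHIJK median was -0.77 and its adjusted p 0.0632, and over all alternatives the adjusted p ran from 1.84e-07 to 0.912, the latter in fry. glnH, mltG, yhiN, fabI and glnG had the smallest p and none passed. edgeR called 0 genes with 40 at an unadjusted p under 0.05, while DESeq2 and limma-voom each called 1, pdeL. The fusion holds only part of pdeL, so that call does not measure a difference in expression.

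The deletion strain with plasmid-borne PdeL was also set against the wild type. yghJ rose from 83.0 ± 6.22 to 438 ± 15.1 CPM, a fitted 5.27-fold rise (SD, n = 3; log2 fold change 2.40 ± 0.23 SE, edgeR adjusted p = 0.000337). fliFGHIJK summed to 40.7 ± 20 CPM against 352 ± 35.6 CPM, an 8.64-fold lower mean (SD, n = 3, two-sided exact permutation p = 0.10, the smallest possible). fliF had a log2 fold change of -3.33 ± 0.63, fliG -3.32 ± 0.57, fliH -2.62 ± 0.48 and fliI -2.50 ± 0.51 (SE), with adjusted p of 0.0888, 0.0639, 0.0886 and 0.150. pdeL itself rose, with a fitted log2 fold change of 8.52 ± 0.62 SE (adjusted p = 0.000337), from 18.6 ± 11.9 CPM to 6987 ± 1571 CPM. The changes of yghJ and the flagellar genes were thus seen at a pdeL transcript level far above that of the wild type. Deleting pdeL gave no called change in yghJ or fliFGHIJK, so this comparison does not show what chromosomal pdeL does.

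The fliFGHIJK list fell against the wild type, with a median of -2.97 (camera adjusted p = 3.68e-21, adjusted p = 0.00702 with an estimated correlation) and all 4 members past the threshold adjusted over the list alone. Without delta-pdeL+PdeL replicate 1 its median was -3.60. The other class 2 list fell, all 19 below 0, 2 past the threshold adjusted over the list alone and a median of -0.895 (camera adjusted p = 4.68e-16, adjusted p = 0.0892 with an estimated correlation). Of these flhB had -1.75 ± 0.37 and fliE -3.26 ± 0.81 (SE), with 0 past the threshold over all genes. The class 3 and chemotaxis list fell, 20 of 22 below 0 with a median of -1.03 (camera adjusted p = 5.72e-07, adjusted p = 0.687 with an estimated correlation), and its median was -1.75 without the libraries numbered 1; number 3 had the lowest sum in both groups. The anaerobic respiration and fermentation list rose, 10 of 12 above 0 with a median of 0.92 (camera adjusted p = 0.0411, adjusted p = 0.280 with an estimated correlation). It was higher in the libraries numbered 1 by a median of 0.59 (camera adjusted p = 0.0384, adjusted p = 0.303 with an estimated correlation). Without them its median was 0.23 (adjusted p = 0.0224). Its formate channel gene focA had 1.86 ± 0.72 (SE). flhB, corA, csgC, wecA and fabI had the smallest p among other genes and none passed in edgeR, while DESeq2 called all 5 among its 12 genes. With a term for the libraries numbered 1 the count was 5, adding fliF, fliG and tnaB. That term takes the same shift of number 1 in every group, but tnaA had 391 counts in PdeL number 1 and 9 in wt+ctrl number 1. Without those libraries tnaB was not called, so its call is not read as an effect of PdeL. The count without them was 7, adding fliF and fliG, which were lower, and ydfZ (2.97), focA (2.34) and cspA (1.60), which were higher.

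All cultures received IPTG, and lacI had 1070 ± 143 CPM in wt+ctrl, 1432 ± 242 in delta-pdeL+ctrl, 1386 ± 181 in delta-pdeL+PdeL and 1189 ± 389 in delta-pdeL+PdeLDBD_cIc (SD, n = 3). No lac gene passed in any comparison, and lacA was not tested. Of the neighbours of pdeL, betA, betB, betI and betT were tested and none passed in any comparison.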

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

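The tests of the libraries numbered 1 in this part were chosen after their values were seen, and the bound of the rRNA test was tightened after its result; the comparison of PdeL with the fusion was planned. Effects that differed between groups in a test of the difference are given here. The fliFGHIJK list fell more with PdeL than with the fusion, by a median log2 of -1.31, and the class 3 and chemotaxis list by -0.505; neither passed with an estimated correlation.

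The shift from numbers 2 and 3 to number 1 was more positive in the deletion strain than in wt+ctrl for the maltose list (median log2 4.35), the galactose and mgl list (2.985), the sugar alcohol and ribose list (2.21) and the heat shock list (0.755). For the ribosomal protein list it was more negative (-0.467). These 5 lists passed camera with the preset correlation and none with an estimated correlation (adjusted p = 0.847 each). Of single genes 1 passed, manZ, a mannose transport gene named after its values were seen (log2 3.0, edgeR adjusted p = 0.0107), with 393, 598 and 399 counts in the deletion-strain libraries numbered 1 and 72 in wt+ctrl number 1. On the wild-type side number 1 is 1 library, so these tests do not separate the strain from that library.

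The carbon uptake pattern was weighed against properties of the libraries. Depth does not account for it, as library 1 was the shallowest in 1 of the 3 deletion-strain groups, while the mean log2 CPM of 30 carbon uptake genes was higher in number 1 of all 3 by 2.23, 2.84 and 3.20. The rRNA share was higher by 12.8 and 11.5 points in delta-pdeL+ctrl and the fusion group, but by 0.465 points with PdeL, and in wt+ctrl it was higher by 9.93 points with carbon uptake higher by 0.567. These last 2 groups go against the rRNA share, each through a single library, so it stays open. The state of the cultures was not tested, since the 4 of 4 carbon uptake lists past the threshold at the preset correlation restate the pattern (0 of 4 pass with an estimated correlation), and the labels give no day or batch.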

How the results depend on the processing

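The fits with a term for the libraries numbered 1, without those 4 libraries, and DESeq2 or limma-voom with a block or that term were chosen after seeing the data. yghJ kept its direction and its side of the threshold in every setting run for PdeL against delta-pdeL+ctrl (log2 2.49 to 2.66, highest adjusted p 0.0120) and against wt+ctrl (2.34 to 2.45, highest 0.00865).

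Deletion against wild type: the count of 0 became 1 with no filter, DESeq2, the replicate block, and DESeq2 with the block or the batch term, and 28 in limma-voom with the block. Leaving out each library gave 0 to 1. pdeL was called at -6.53 with no filter, -5.93 in DESeq2, -6.54 with the block, -5.84 and -5.87 in DESeq2 with the block and the batch term, and -4.43 in limma-voom with the block; leaving out each library gave -6.92 to -5.97. The fliFGHIJK median of -0.04 turned to 0.009 with library size only, 0.011 with the stricter filter and 0.232 without number 1, and ran from -0.22 to 0.18 without each library. fliG turned to 0.208 and fliI to 0.034 without number 1, and without each library ran from -0.344 to 0.071 and -0.456 to 0.092. fliH was 0.000 with RLE factors, -0.05 in limma-voom, -0.018 without ribosomal RNA, -0.004 and -0.014 in DESeq2 with the block and batch term, -0.062 in limma-voom with the block and -0.22 to 0.29 without each library. None of these flagellar values was past the threshold.

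PdeL against deletion: the count of 2 was 4 with no filter and without ribosomal RNA, 5 in DESeq2, with the batch term and in limma-voom with the block, 6 with the block, 9 without number 1, 19 and 11 in DESeq2 with the block and batch term, and 2 to 4 without each library (4 without delta-pdeL+PdeL replicate 1). Fusion against deletion: the count of 2 was 1 in limma-voom and with only the groups compared, and 4 in DESeq2 with the block; pdeL was 10.175 in limma-voom. Shared calls moved from 2 to 1, 1 and 4 in the same settings, and were 3, with wecA, in DESeq2, with the block, with the batch term, and in DESeq2 with the batch term and limma-voom with the block.

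PdeL against fusion: the count of 0 was 1, pdeL, in DESeq2, limma-voom, the block, the batch term, without number 1 and the combined fits. pdeL was 2.76 in DESeq2, 2.80 in limma-voom, 2.83 with the block, 2.81 with the batch term, 2.55 without number 1, 2.825 and 2.816 in DESeq2 with the block and batch term, and 2.802 in limma-voom with the block. These pdeL values set the full-length gene against a part of it. The fliFGHIJK median ran from -1.57 to -0.766, and cheR from -2.04 to 0.537, without each library. PdeL against wild type: the count of 2 was 4 with no filter and with the block, 12 in DESeq2, 5 with the batch term, 7 without number 1, 28 and 16 in DESeq2 with the block and batch term, and 63 in limma-voom with the block. The cause of these changes was not tested.

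Lists past the threshold, in the order estimated correlation, fry, block, batch term and without number 1, moved from 0 to 0, 0, 2, 3 and 0 (deletion), from 3 to 1, 1, 3, 3 and 4 (PdeL), from 4 to 1, 0, 4, 4 and 3 (fusion), from 2 to 0, 0, 4, 4 and 4 (PdeL against fusion) and from 4 to 1, 1, 6, 7 and 4 (PdeL against wild type). With the fusion, wecA was past the threshold in 7 of its alternatives, with adjusted p from 0.000403 upward. The single genes named kept their direction and side in 1565 of the values, passed the threshold in 94, lost it in 1 (yghJ with the fusion, only the groups compared) and turned in 16.

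Same-numbered libraries deviated together at over 0.1 in 17 of 18 pairs, and the last, wt+ctrl 2 with delta-pdeL+PdeL 2, was 0.073. By the bound fixed beforehand, which asks for every pair of groups, the numbers were not treated as pairing the samples. That 1 pair missed the bound does not show that the samples are unpaired. Blocked counts had been seen before these correlations. The 9 pairs among the deletion-strain groups ran from 0.31 to 0.79. Each of the 12 libraries correlated best with its own number, a hint from the data and not the design. With the block, fliF (adjusted p = 0.00674), fliG (0.0153), wecA (0.028) and flgL (0.0283) were called for PdeL against deletion, wecA (0.0172) for the fusion, and fliF and fliG (0.0117 each) for PdeL against wild type, besides pdeL and yghJ. The fliFGHIJK list with the block and an estimated correlation had an adjusted p of 0.0645, 0.226 and 0.0733 in these 3 comparisons and was not called.

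Depth limits which genes could be tested, 1911 in all, with fliJ and fliK below the filter. Variation between libraries limits the calls among them: the common biological coefficient of variation was 0.486, or 0.28 with the block. In simulations with library effects shared by number, at the same depth, the block recovered 29.3%, 79.4% and 93.3% of 2-fold, 4-fold and 8-fold changes. Of its calls 4.5% were false, and the edgeR test without it recovered 4.2%, 49.0% and 73.3%. These counts were drawn from the blocked fit itself, so the block was bound to do better there. The simulations therefore do not show that the numbers pair the samples.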

Other observations

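The tests in this part were chosen after the values were seen, except the splits of the libraries, and the bound on overlapping libraries was added after its result was seen. The curli genes, which make an amyloid fibre of the biofilm matrix, were a list fixed beforehand with too few tested members for a list test, and their sum was added later. Their 7 genes summed to 91.5 ± 5.27 CPM in delta-pdeL+ctrl, 98.6 ± 36.1 in wt+ctrl, 36.6 ± 7.24 with PdeL and 35.9 ± 8.27 with the fusion (SD, n = 3). Each protein against the deletion control gave a two-sided exact permutation p of 0.10, the smallest possible. These sums are mostly 1 gene, csgC, with 76.1 ± 14.4, 93.5 ± 33.7, 29.2 ± 11.5 and 32.8 ± 8.86 CPM in the same order, and the other 6 genes held 1 to 14 counts per library, too few to read. The flagellar master regulator genes flhD and flhC summed to 85.0 ± 34.9 CPM in delta-pdeL+ctrl, 60.5 ± 28.2 in wt+ctrl, 26.5 ± 17.1 with PdeL and 30.5 ± 14.4 with the fusion (SD, n = 3), with an exact permutation p of 0.10 for PdeL and 0.20 for the fusion against the deletion control. The sums with PdeL rest on 25, 4 and 20 counts. PdeL against wt+ctrl gave an exact permutation p of 0.30, with ratios of 0.416, 0.114 and 1.09 in numbers 1, 2 and 3. These sums therefore do not establish a fall.

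The wec operon makes enterobacterial common antigen, a surface glycolipid, and was not among the lists fixed beforehand; it was picked because wecA, wzzE, wecB and wecE had small p. Its 12 genes summed to 524 ± 70.7 CPM in delta-pdeL+ctrl, 477 ± 26.0 in wt+ctrl, 249 ± 38.3 with PdeL and 227 ± 54.2 with the fusion (SD, n = 3). Each protein against the deletion control gave a two-sided exact permutation p of 0.10, the smallest possible. The gene upstream, rho, had 366 ± 34.4 CPM in delta-pdeL+ctrl, 429 ± 62.2 with PdeL and 341 ± 109 with the fusion. The summed operon had a ratio of PdeL to the deletion control of 0.467, 0.598 and 0.384 in the libraries numbered 1, 2 and 3.

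For the wec operon, the fall was not confined to the comparison with the deletion control. Against wt+ctrl the higher of the medians for the proteins was -0.684, and the libraries did not overlap. Of the single genes tested, 12.8% likewise did not overlap between PdeL and wt+ctrl, where 10% would by chance. The lack of overlap thus does not by itself exclude chance. Without the libraries numbered 1 the higher median was -0.936 over 10 genes, so the difference did not rest on those libraries alone. Co-transcribed genes are not independent, so intervals over genes are too narrow. Selection and chance stay open, since the operon was picked by small p in these same libraries and was then tested in them. It also stays open that making any plasmid-borne protein may lower the operon, because 0 groups carried an unrelated protein.

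For the flagellar genes outside fliFGHIJK, the median without the libraries numbered 1 was -1.70 with PdeL and -1.24 with the fusion. Against the deletion control the class 2 sums had ratios of 0.701, 0.446 and 0.222 with PdeL in numbers 1, 2 and 3. The fall was thus smallest in number 1 and did not rest on it, and leaving it out was bound to keep the fall. The libraries numbered 3, with the largest fall, were not left out together. For the class 2 genes, the fall was not confined to the comparison with the deletion control. Against wt+ctrl the higher median was -0.747 and the libraries did not overlap, which 3 against 3 libraries can also show by chance. For the class 3 and chemotaxis genes the higher median against wt+ctrl was -0.449 and the libraries overlapped. High control libraries can therefore not be told apart there from an effect of the proteins. The same gap of 0 groups with an unrelated protein leaves any plasmid-borne protein open as a possible explanation.

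Splits of 3 against 3 libraries number 10, too few for a share under 0.05. The 3 comparisons with 2 genes had them in 1 split, the real one, and the highest of the other splits gave 0. For the comparisons with 0 genes, all 10 splits gave 0.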
